A study of Danio rerio with 7 samples.

How the data were processed

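Zebrafish embryos at 50% epiboly, a blastula to gastrula stage at which the blastoderm has spread over part of the yolk, were profiled by droplet-based single-cell RNA sequencing (10x Genomics). Per the labels, treated embryos had received mRNA of psMEK, a light-controlled form of the kinase MEK, and light, and untreated embryos were wild type and uninjected. MEK activates ERK, the last kinase of the MAPK cascade downstream of FGF receptors. Injection, the construct and light therefore differ together between the groups, and whether untreated embryos were lit is not given in the sources used here. Embryos were deyolked and dissociated by hand per the labels' protocols. Groups were taken from the sample titles, which give 3 untreated and 4 treated libraries in 4 batches, whereas the text on the study design gives the opposite numbers. Untreated libraries 1, 2 and 3 came from batches 1, 3 and 4, treated library 4 from batch 2, treated libraries 5 and 6 from batch 3 and treated library 7 from batch 4. No label says whether the libraries came from separate clutches, so p-values measure the spread between these libraries, which may be in part technical.

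The authors deposited raw UMI counts per gene and cell barcode, not normalized. Per the file headers, the count matrices of batches 1 and 2 were made with Cell Ranger 4.0.0 and those of batches 3 and 4 with Cell Ranger 7.1.0, while the submitters' processing notes name Cell Ranger 4.0.0 and the genome build GRCz11. The feature tables list 32520 genes for batches 1 and 2 and 25432 for batches 3 and 4, all of the latter also in the former, and the annotation release and the handling of intronic reads are not given in the sources used here. Only the 25432 shared genes were used. They hold 94.0% and 95.5% of the UMIs of libraries 1 and 4. Gene identity was taken from the deposited Ensembl IDs and symbols, and no coordinates are given because the reference table at hand is of another build. The lowest UMI total per deposited barcode was 500 to 507 in every library.

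Cells were kept with at least 1000 detected genes and at most 10% mitochondrial UMIs. Doublets were scored with Scrublet in scanpy 1.11.5, and because its own threshold marked at most 2 cells in a library, the highest-scoring cells were removed at an expected rate of 0.8% per 1000 barcodes. This left 5826, 3993 and 1783 untreated cells in libraries 1 to 3 and 3397, 4278, 3968 and 1554 treated cells in libraries 4 to 7. Median UMIs per kept cell ranged from 4407 in library 3 to 29217 in library 4. A joint clustering split by feature table, with 28 of 31 clusters drawing at least 90% of their cells from 1 table, so each library was clustered alone on 2000 variable genes, 30 principal components and a graph of 15 neighbours (Leiden resolution 1.0). Clusters were named from marker lists fixed before the data were examined, under thresholds set after seeing the clusters: at least 3 markers raised by a log2 fold of at least 1.0, a median marker log2 fold of at least 1.5, and no more than 1.5 below the highest cluster. Most detected markers of the list also had to be raised, and no other class could have more markers among the 10 leading genes. A cluster of low depth needed a marker of its own class among those genes. Clusters led by marginal, axial, endodermal or dorsal forerunner markers were called mesendoderm-like. All other cells stayed unnamed, including ectoderm, for which markers did not separate clusters. These rules together kept out clusters led by enveloping layer markers that held 7.86%, 2.48% and 4.09% of the cells of libraries 1 to 3 and 14.7%, 24.8%, 17.0% and 41.3% of libraries 4 to 7, and clusters led by mesendoderm markers that held 22.7%, 3.73% and 13.7% against 8.98%, 11.2%, 19.0% and 0%.

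Cells are not replicates, so the deposited counts were summed per library over all kept cells and within each class. The sums were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM normalization, filterByExpr) with the feature table as covariate over all 7 libraries, and p was adjusted by Benjamini-Hochberg with a threshold of 0.05. Expression values are CPM (the usual count scale of edgeR) of these sums with TMM-adjusted library sizes, as means with SDs over libraries. A batch term would leave out libraries 1 and 4, since batches 1 and 2 hold 1 group each, so a fit with batch as replicate block over batches 3 and 4 was an alternative. The batch is named in the labels. Deviations from group means correlated at 0.378, 0.613 and 0.658 for the 3 pairs of a treated and an untreated library of the same batch, and negatively for pairs of different batches. With only 2 untreated libraries there, these correlations are tied to each other. Treated libraries 5 and 6 share a batch. Their counts differed beyond sampling noise (chi-square per degree of freedom 28.0, against 72.6 to 519 for other pairs within a group), so they were not treated as 1 library and both were kept. This was the lowest value of those pairs and does not show that they came from separate embryos or suspensions. With both summed into 1 sample, 59 genes were higher and 17 lower, against 95 and 34 with both kept.

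The 25 gene lists were fixed before the data were examined, and 330 of their 338 entries matched 1 deposited gene. They were tested with fry of limma 3.58.1, a rotation test of whether members move on balance in 1 direction. Its mixed test, which asks whether members move in either direction, was run beside it. A fry p is of the directional test unless called mixed. Camera was run at a preset correlation of 0.01 and at an estimated correlation. The difference in effect between enveloping layer-like and all other cells was tested as an interaction in edgeR with the library as block. That fit had no term for a class difference that varies with the feature table. Named genes followed a rule fixed beforehand: dusp6, spry4, etv4, il17rd, tbxta and map2k1 always, the 12 largest increases and 12 largest decreases past the threshold with a mean CPM of at least 10 and the same sign in all 3 differences between a treated and an untreated library or pair of the same feature table, up to 4 members of each list, and 5 genes per direction and class. Among whole-embryo genes meeting the rule, 4 of 57 increases and 1 of 23 decreases had clone names and were counted but not named. 1 further gene taken by the rule is counted in the totals and not reported here. The cells left unnamed were tested like a class, a choice made after seeing the data.

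Shares of cells were compared between libraries with a two-sided exact permutation test. The 35 splits of 7 libraries into 3 and 4 allow no p below 0.0571, so no such test can pass 0.05. Intervals are exact binomial at 95% and cover counting error only. For shares of cells with a UMI, each cell was thinned to 3000 UMIs, which kept 5373, 2922 and 1235 untreated and 3239, 3704, 3607 and 1253 treated cells. For the distance measure, thinned and normalized profiles were centred within each feature table on the midpoint of the group means, and the mean distance from 1000 cells per library to the 5 nearest untreated cells of the other feature table was taken. Because that centring uses the group labels, its permutation p is not strictly exact.

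The tests were tried on simulated counts with the real library sizes, mean levels and trended dispersion. Genes were drawn independently and without an effect of feature table or batch, so the rates hold for that setting only. For the whole embryo (18525 genes), edgeR recovered 29% of genes changed by 2-fold and 86% of those changed by 4-fold, with 2 unchanged genes called. For enveloping layer-like cells (12322 genes) it recovered 23% and 84%, for mesendoderm-like cells (13646 genes) 45% and 94%, and for the interaction 3% and 59%. The simulated interaction covered 11982 genes with a mean of at least 10 counts per library in enveloping layer-like sums, and the real test 17698 genes, so its recovery among genes with fewer counts was not measured. On simulated lists, fry called 10 of 10 raised lists and 1 of 10 unchanged lists. Their members were not correlated, while the real lists that passed had estimated correlations of 0.22 to 0.34. The rate of false calls among correlated members was not measured. Alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, no covariate, the batch block, libraries 5 and 6 summed, all barcodes, doublets kept, other Leiden resolutions, other depths and leaving out each library. Some were added after seeing the data: leaving out both batch 4 libraries, sums of thinned cells, leaving out stressed or dying cells-like clusters, DESeq2 size factors in edgeR for the classes, and the remaining alternatives of single genes, lists and ERK shares.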

Results

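Single-cell transcriptomes of whole zebrafish embryos at 50% epiboly were compared between 4 libraries of embryos given light-controlled MEK and light (treated) and 3 libraries of uninjected wild-type embryos (untreated). The deposited matrices held 91832629, 33004306 and 22703910 UMIs in untreated libraries 1 to 3, and 117463473, 41009355, 38379504 and 44144323 in treated libraries 4 to 7. The first principal component of the library sums, 71.6% of the variance, parted the libraries by feature table, and the second, 13.0%, parted the groups. The comparison asks how forced activity of the MAPK pathway changes gene expression and cell states in the early embryo.

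Genes that ERK signalling switches on as its own feedback were higher in treated embryos. spry4 (ENSDARG00000068732), a feedback inhibitor of receptor tyrosine kinase signalling, rose from 38.1 ± 9.17 CPM (SD, n = 3) to 165 ± 17.2 CPM (SD, n = 4), a log2 fold change of 2.12 with a standard error of 0.20 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.016). dusp6 (ENSDARG00000070914), the phosphatase that inactivates ERK, rose from 87.3 ± 19.1 to 230 ± 30.8 CPM, log2 1.40 with a standard error of 0.19 (edgeR adjusted p = 0.032). dusp5, another ERK phosphatase, rose from 0.603 ± 0.265 to 38.8 ± 38.3 CPM and spry2 from 35.8 ± 4.45 to 76.6 ± 13.3 CPM (adjusted p = 0.054 for spry2 in edgeR with batch as replicate block). The ETS factor gene etv4 (log2 0.88, edgeR adjusted p = 0.062) and il17rd, an FGF antagonist (log2 0.83, adjusted p = 0.121), missed the threshold. Of the 16 measured members of the list of ERK feedback regulators and ETS factors, 4 rose over all genes tested and 6 when adjusted over the list alone, none fell, and the median log2 fold change was 0.72. The list rose on balance (fry, adjusted p = 0.043), but not with an estimated correlation (camera, adjusted p = 0.30). The gene map2k1, which encodes MEK1, was at 4.36 ± 0.444 and 8.37 ± 1.35 CPM (log2 0.95, edgeR adjusted p = 0.128). Whether reads of the injected mRNA were counted under it was not tested.

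**Figure D1:**
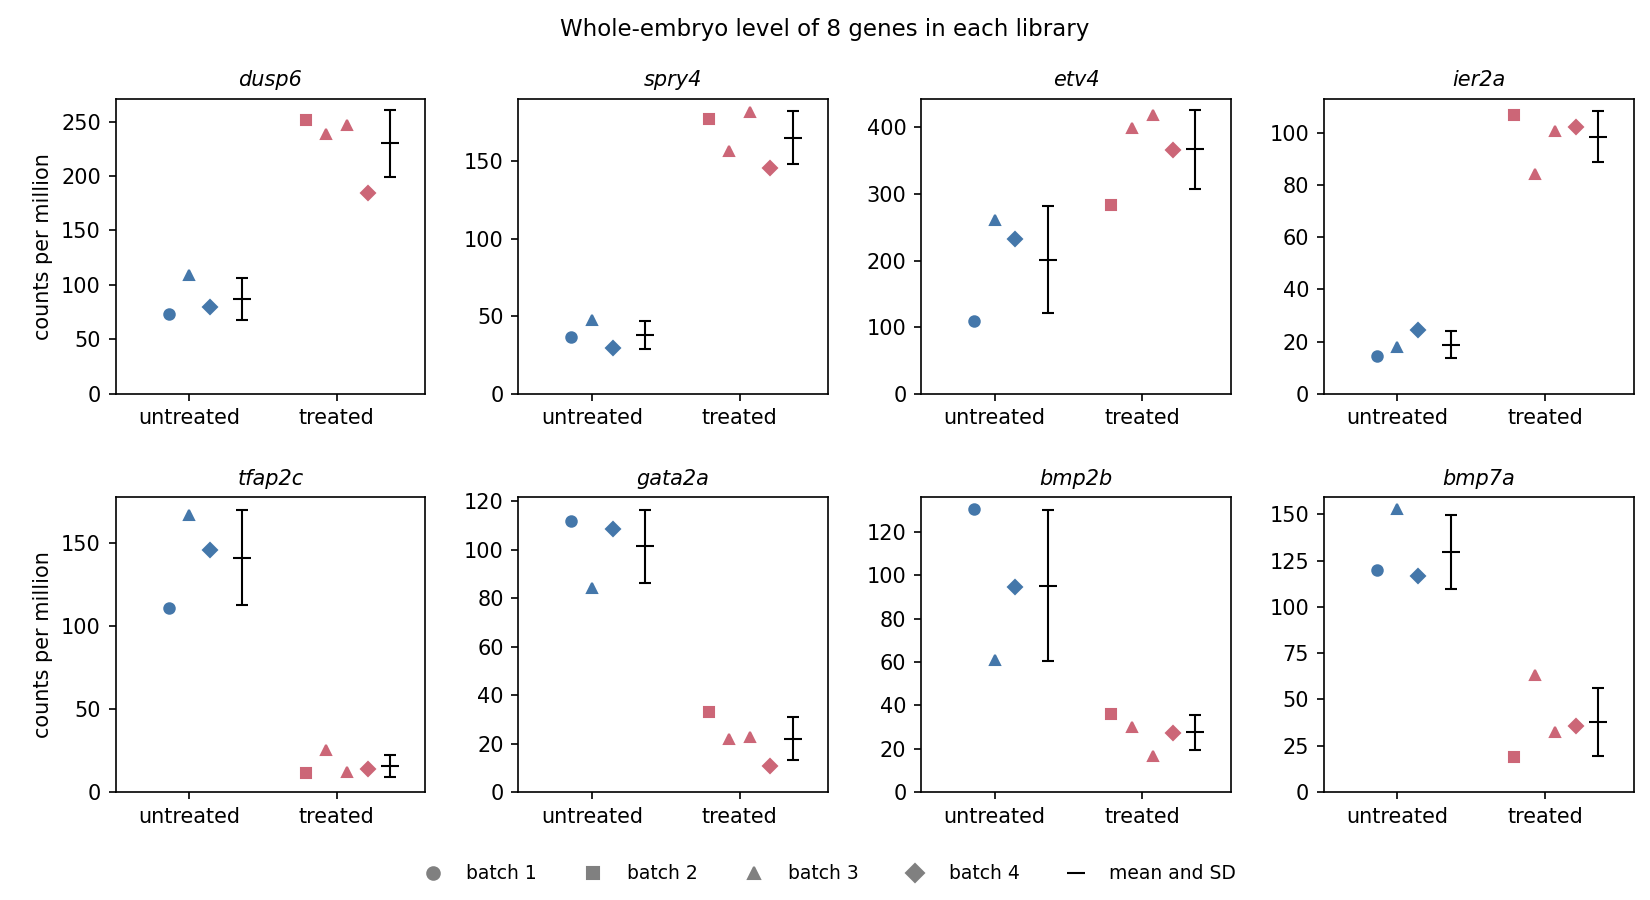
Expression level in the summed cells of each library for 8 genes (CPM, vertical axes, linear, from 0), for untreated and treated libraries; each point is a library, its shape gives the batch, and the black bar is the mean with SD. Every treated library lies above the untreated ones for dusp6, spry4 and ier2a and below them for tfap2c, gata2a, bmp2b and bmp7a.

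Immediate early genes, the first transcripts induced by MAPK signalling, also rose. ier2a rose from 18.9 ± 5.04 to 98.5 ± 9.76 CPM (log2 2.39), fosl1a, a subunit of the transcription factor AP-1, from 2.47 ± 1.86 to 22.5 ± 4.03 CPM (log2 3.27), and junbb and btg2 by log2 1.91 and 0.84 (edgeR adjusted p = 0.063 and 0.054 with batch as replicate block). These were the 4 of 16 measured members that passed over all genes. Adjusted over the list alone, 10 rose and 1 fell. The list passed in fry (adjusted p = 0.043) and did not with an estimated correlation (adjusted p = 0.24) or with batch as replicate block (adjusted p = 0.090).

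Genes of the ventral side and of the future epidermis fell. bmp2b and bmp7a, which encode the BMP ligands that pattern the ventral embryo, fell from 95.3 ± 34.8 to 27.5 ± 8.02 CPM and from 130 ± 19.9 to 37.6 ± 18.4 CPM. The BMP-binding factor gene bmper (log2 -2.02), the inhibitory Smad gene smad7 (log2 -1.60) and the ventral transcription factor gene gata2a (log2 -2.20) fell with them. With batch as replicate block, on 5 libraries, bmp2b, bmp7a, smad7 and gata2a no longer passed (edgeR adjusted p = 0.089, 0.085, 0.085 and 0.061), and bmper did (0.047). On the list of BMP ligands, targets and ventral genes, 5 of 18 members fell over all genes and 11 when adjusted over the list alone, with 1 higher; the median log2 fold change was -1.66. On the list of non-neural ectoderm, which shares gata2a, 3 of 8 fell. These were tfap2c, an epidermal AP-2 factor gene (141 ± 28.5 to 15.5 ± 6.49 CPM, log2 -3.24, edgeR adjusted p = 0.013), tp63, the regulator of epidermal stem cells (log2 -2.61, edgeR adjusted p = 0.017), and gata2a. Adjusted over the list alone, 5 fell. Both lists fell in fry (adjusted p = 0.043 each). With an estimated correlation both had an adjusted p = 0.24, and with batch as replicate block 0.14 and 0.090. Markers of the enveloping layer, the outer epithelium, lay on the opposite side. All 13 measured members had a log2 fold change above 0, from 0.09 to 1.66 with a median of 0.93, and none passed over all genes or adjusted over the list alone (fry, adjusted p = 0.69; camera, adjusted p = 0.0017 with the preset and 0.75 with an estimated correlation).

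Among ectodermal genes, 3 of 13 measured neural members rose, among them foxb1a (20.2 ± 11.2 to 121 ± 16.5 CPM) and sox11a (log2 1.01). Adjusted over the list alone, 3 rose and 1 fell. The neural list as a whole did not pass (fry, adjusted p = 0.24), and its median log2 fold change was -0.11 while its fry direction was up. Among Nodal genes, tdgf1, the Nodal co-receptor gene, and dact2, an antagonist of Nodal signalling, rose by log2 1.33 and 1.39 (edgeR adjusted p = 0.055 and 0.042 with batch as replicate block). The other 15 of the 17 Nodal genes did not pass, and adjusted over the list alone 3 rose and 4 fell. The list had a median log2 fold change of -0.37 and did not pass (fry, direction down, adjusted p = 0.88). None of the 23 marginal mesoderm genes passed, with tbxta, the Brachyury gene, at 471 ± 23.8 and 666 ± 194 CPM (log2 0.50, edgeR adjusted p = 0.306). No member passed edgeR among the 6 FGF ligands, 21 RAS-MAPK components and FGF receptors, 12 organizer, 9 Wnt target, 6 retinoic acid, 8 endoderm, 5 dorsal forerunner, 7 germ cell, 11 maternal, 20 cell cycle, 15 Notch and 13 mitochondrial genes. Adjusted over the list alone, 3 organizer genes rose, and 2 and 3 of the RAS-MAPK list, 1 and 2 of the retinoic acid list, 2 and 2 of the dorsal forerunner list and 2 and 1 of the Notch list rose and fell. 2 endoderm genes and 1 maternal gene fell by that measure, and no member of the mesoderm, FGF ligand, Wnt, germ cell, cell cycle or mitochondrial lists passed it. The organizer list had a median log2 fold change of -0.08 and the direction up in fry, and the retinoic acid list a median of -0.07, a mean of 0.11 on the log2 CPM scale and the direction down. The fry adjusted p of these lists and of the mesoderm list ran from 0.417 for endoderm to 0.995 for the cell cycle. In the mixed test of fry the neural (adjusted p = 0.0025), Nodal (0.0034), RAS-MAPK (0.0030) and retinoic acid (0.0034) lists passed. The dorsal forerunner (0.0030), Notch (0.021) and organizer (0.025) lists passed it too, so members of these lists moved without 1 shared direction. The mesoderm (0.078), endoderm (0.073) and Wnt (0.12) lists did not pass it. The mixed test does not compare a list with the remaining genes, so passing it does not set a list apart from them. Over all 18525 genes, 1446 were higher and 1416 lower at an unadjusted p under 0.05 in edgeR.

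Of the 12 measured p53 targets, bbc3, an apoptosis activator gene, and isg15, a ubiquitin-like modifier gene also induced by interferon, rose by log2 1.87 and 3.35, and 11 rose when adjusted over the list alone (fry, adjusted p = 0.043; with an estimated correlation, adjusted p = 0.24). With batch as replicate block bbc3 and isg15 rose by log2 1.65 and 3.48 and did not pass (edgeR adjusted p = 0.068 and 0.095). isg15 was also the 1 member of the 8 measured interferon genes that rose, against 4 adjusted over the list alone (fry, adjusted p = 0.053). Of 13 heat shock and unfolded protein genes, hspb1, which encodes a small heat shock protein, rose from 3862 ± 714 to 8224 ± 883 CPM, and hsp70.1 and hsp70l also rose. Adjusted over the list alone 6 rose, and the list did not pass (fry, adjusted p = 0.064). The inducible chaperone genes hsp70.1, hsp70.2, hsp70.3, hsp70l and hspa8b are near-identical relatives between which the counting may have split reads, so their single values are uncertain. hsp70.3 stood at 1850 CPM in treated library 4 and at 126 to 160 CPM in treated libraries 5 to 7, against 14.1 ± 6.08 CPM in untreated libraries. Of the 6 measured yolk syncytial layer genes, the apolipoprotein gene apoeb fell from 1833 ± 334 to 520 ± 148 CPM, and 2 fell adjusted over the list alone (fry for the list, adjusted p = 0.516). Of 15 cell adhesion and movement genes, the chemokine gene cxcl12a fell by 1.37 on the log2 scale, and 1 rose and 2 fell adjusted over the list alone (fry, direction up with a median of -0.02, adjusted p = 0.995). With batch as replicate block apoeb and cxcl12a did not pass (edgeR adjusted p = 0.054 and 0.11). In the mixed test of fry the interferon (adjusted p = 0.011), heat shock (0.011) and cell adhesion (0.0047) lists passed. The yolk syncytial layer list (0.074) did not.

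**Figure D2:**
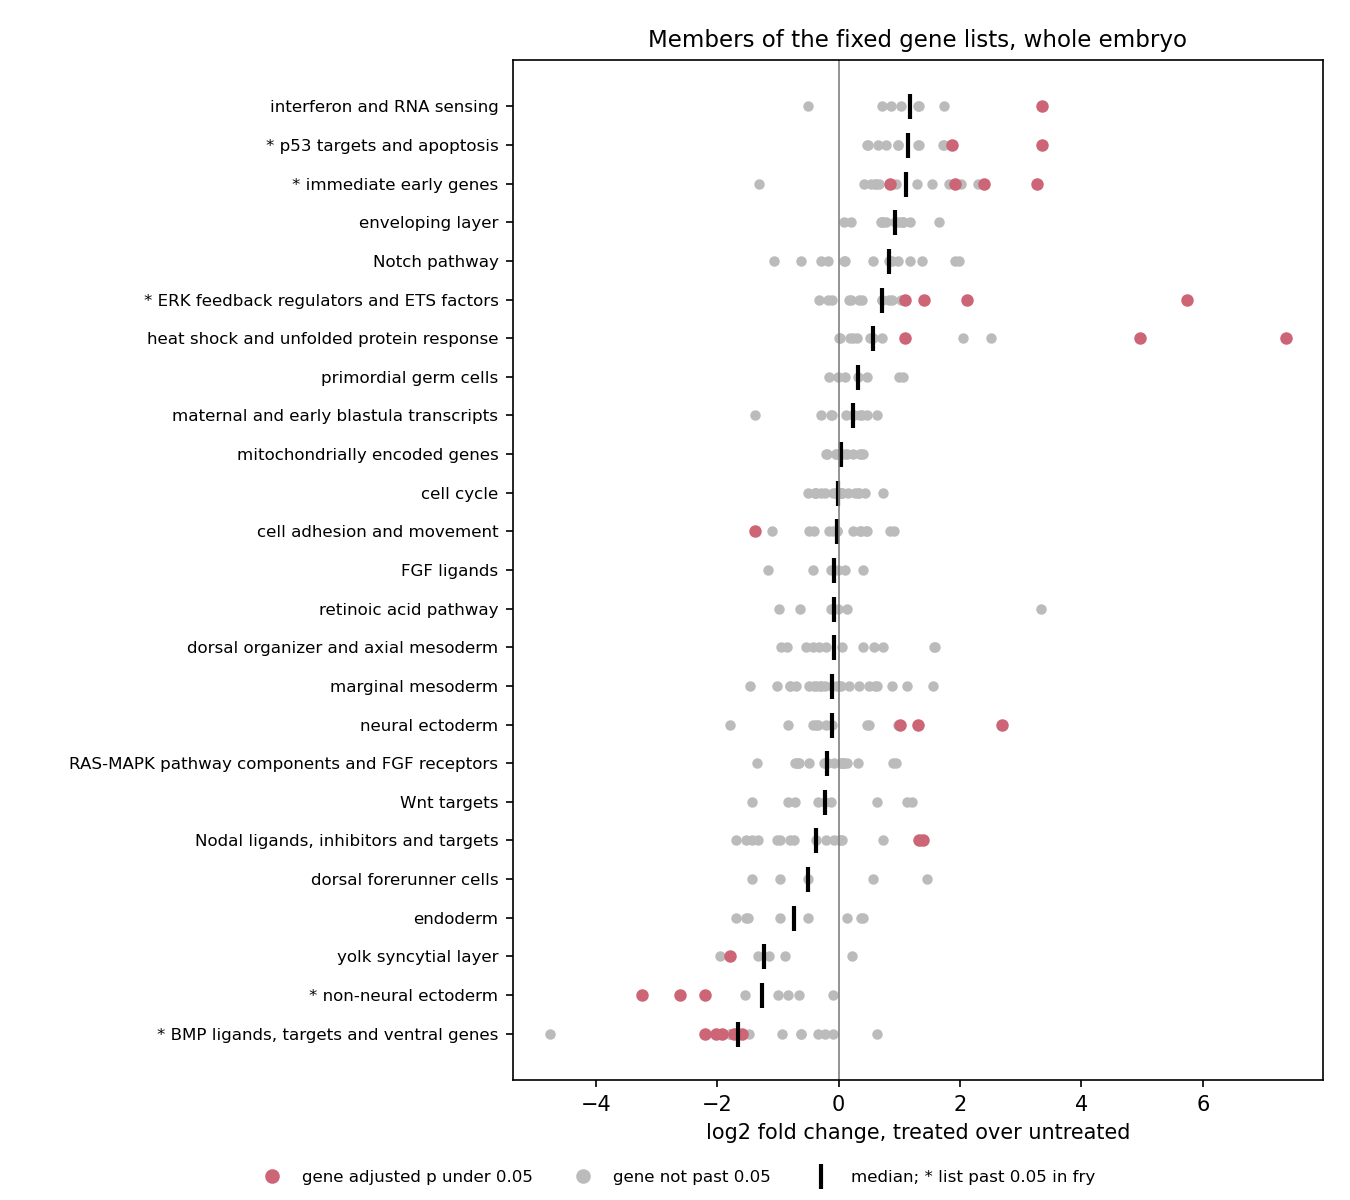
Log2 fold change of treated over untreated (horizontal axis) for each measured member of the 25 fixed gene lists, ordered by median; red points are genes with an adjusted p under 0.05, grey points the others, black ticks the medians, and a star marks lists past 0.05 in fry. The median of the BMP list lies at -1.66 and that of the p53 list at 1.15.

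Over all 18525 genes tested, 95 were higher and 34 lower in treated embryos (edgeR, adjusted p under 0.05). The largest increases by the fixed rule were she (log2 7.32), klhl4 (6.36), aqp8a.1, an aquaporin gene (5.91), dusp5 (5.74), tmem119b (5.44), hspa8b (5.08), hsp70.1 (4.97), hsp70.3 (4.52), lrrn3a (3.87), isg15 (3.35), fosl1a (3.27) and foxb1a (2.69). The largest decreases were kazald2 (log2 -3.45), tfap2c (-3.24), gata2a (-2.20), bmper (-2.02), cbfa2t2 (-1.95), bmp7a (-1.92), slc12a2, an ion cotransporter gene (-1.86), apoeb (-1.79), alpl, alkaline phosphatase (-1.78), bmp2b (-1.71), smad7 (-1.60) and mfsd2ab (-1.54). Besides the genes given above, tmem119b, slc12a2, alpl and mfsd2ab did not pass with batch as replicate block (edgeR adjusted p = 0.089, 0.0502, 0.060 and 0.063). The counts depended on the libraries kept: 1 higher and 0 lower without untreated library 1 and the same without treated library 4, against 164 and 118 without untreated library 2. Leaving out library 1 or 4 leaves 1 library on that feature table. The covariate then fits that library exactly, so it adds nothing to the estimated effect. Those fits therefore compare the libraries of batches 3 and 4 alone. Without library 3, 5, 6 or 7 the counts were 14 and 5, 48 and 18, 17 and 3, and 32 and 12. With batch as replicate block they were 60 and 26 (42 and 12 shared), with DESeq2 599 and 339, and without both batch 4 libraries or without the covariate 0 and 0 (517 and 257 at an unadjusted p under 0.05 without the covariate, 2126 and 1673 without batch 4).

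Within enveloping layer-like cells, the outer epithelium of the embryo, foxd3, a transcription factor gene of pluripotent and neural crest cells, rose from 7.42 ± 3.38 to 115 ± 88.7 CPM, and dusp5 from 1.57 ± 2.22 to 92.1 ± 65.2 CPM. aqp8a.1, hsp70.2 and hspa8b rose by log2 6.01, 6.02 and 5.41. These sizes are uncertain, as no untreated library had more than 2.56 CPM of any of them and libraries 2 and 3 had none of aqp8a.1 and hspa8b. Library 4 also weighed heavily, with hspa8b at 106 CPM there and at 4.71, 3.01 and 1.47 CPM in treated libraries 5 to 7. For hsp70.2 these were 137 CPM and 23.8, 8.87 and 2.64 CPM. In library 7 hspa8b lay below untreated library 1 (2.56 CPM). With batch as replicate block aqp8a.1 rose by log2 10.3 and hsp70.2 by 4.39, and hspa8b was not tested. tfap2c (log2 -3.18), the BMP target bambia (-2.22), bmp7a (-2.17), the metalloprotease gene tll1 (-2.14) and klf2a (-1.85) fell. In all, 37 genes were higher and 6 lower of 12322 tested (edgeR). The count was 0 without library 1 or without library 4, 93 and 42, 7 and 0, 13 and 1, 5 and 0, and 88 and 13 without libraries 2, 3, 5, 6 and 7, and 196 and 111 with batch as replicate block, and 1 other split of the libraries called 136 and 17.

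Within mesendoderm-like cells, named from marginal, axial, endodermal or dorsal forerunner markers, aqp8a.1 rose from 2.53 ± 1.29 to 42.6 ± 14.8 CPM and hsp70.3 by log2 3.34. The tight junction gene cldnb, babam2 and ifi45 rose by log2 1.91, 1.87 and 1.77. tfap2c fell from 46.2 ± 8.14 to 8.44 ± 2.63 CPM, slc12a2 by 1.21 on the log2 scale, and gata6, an endoderm factor gene and itself a marker of the class, by 1.71. These were 8 of the 10 genes called, 7 higher and 3 lower of 13646 tested (edgeR), a count that was 0 without library 1 or 4, 88 and 85 without library 2 and 17 and 11 with batch as replicate block. Without library 3 it was 6 and 1, without 5 it was 5 and 3, and without 6 or 7 it was 3 and 1. With the block, hsp70.3, babam2, ifi45, gata6 and slc12a2 did not pass (edgeR adjusted p from 0.052 to 0.085). In the unnamed cells, those outside the named classes, 241 genes were higher and 83 lower of 16854 (edgeR). The count was 34 and 10 without library 1, 33 and 14 without library 4, 318 and 183 without library 2, 128 and 31 without library 6, 88 and 28 without library 7 and 2 and 2 without the covariate. she, klhl4, lmo2, a blood and vessel factor gene, and uts1 rose by log2 7.52, 6.78, 6.48 and 6.56, and szl, a BMP target, kazald2, gata2a, tfap2c and klf2b fell by log2 5.18, 3.67, 3.64, 3.30 and 2.74, with szl at an adjusted p = 0.071 in edgeR with batch as replicate block.

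The treatment effect differed between enveloping layer-like cells and all other cells for 1 of 17698 genes, gata2a. A joint fit gave a difference of 2.56 on the log2 scale with a standard error of 0.24 (edgeR interaction, adjusted p = 0.0185). In separate fits the log2 fold change was -0.84 in the former (edgeR adjusted p = 0.277), which did not pass, and -3.31 in the others (adjusted p = 0.0088). The count fell to 0 without any of libraries 2, 3, 5, 6 or 7.

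More treated cells held a UMI of some ERK feedback genes at equal depth. At 3000 UMIs per cell, 15.9%, 27.9% and 19.0% of the cells of untreated libraries 1 to 3 and 40.1%, 49.7%, 49.3% and 41.7% of treated libraries 4 to 7 held a dusp6 UMI, and 9.86% ± 2.36 (SD, n = 3) and 33.6% ± 3.93 (SD, n = 4) a spry4 UMI (exact permutation p = 0.0571, adjusted over 8 measures p = 0.0762, for each). spry2 and etv4 also separated the groups (10.4% ± 2.20 and 19.6% ± 1.82, and 39.8% ± 12.8 and 61.9% ± 8.91), while etv5b (38.6% ± 3.87 and 44.7% ± 8.63, exact permutation p = 0.343) and il17rd (22.6% ± 12.1 and 36.8% ± 12.6, p = 0.171) did not. The etv5b share differed by 0.896 percentage points within batch 3 and -0.349 within batch 4, and the il17rd share by 10.8 and 15.3. The etv4 groups lay close, with 48.7% in treated library 4 and 47.8% in untreated library 2, and overlapped with predicted doublets kept, an alternative added after seeing the data (45.5% and 49.3%, exact permutation p = 0.171). Any of the 6 genes was found in 75.6% ± 8.57 and 92.3% ± 1.59 of cells (exact permutation p = 0.0571), a difference of 16.7 percentage points over all libraries, 11.4 within batch 3 and 13.3 within batch 4. Without thinning the shares were 88.6% and 97.7%, and il17rd separated the groups as well. In untreated enveloping layer-like cells, where FGF targets should be low, 8.43% ± 1.96 held a dusp6 UMI. In treated ones 29.0% ± 9.59 did, while mesendoderm-like cells, which receive FGF and Nodal signals, had 30.7% ± 7.70 and 35.2% ± 2.56. The difference in dusp6 share between the groups was 23.8 percentage points larger in unnamed than in mesendoderm-like cells (21.9 within batch 3, 11.5 within batch 4) and 16.1 larger in enveloping layer-like cells (8.06 and 22.1; exact permutation p = 0.0571, the smallest possible, and 0.0975 adjusted over 29 measures, for each). For spry4 these were 16.4 and 7.97 and for etv4 15.8 and 9.91, with p = 0.0571 for unnamed and p = 0.114 and 0.514 for enveloping layer-like cells (exact permutation). Free RNA was not measured apart from cells, and the level of these genes in the summed cells rose too, so a share of treated cells with a UMI is not a share of cells expressing the gene.

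**Figure D3:**
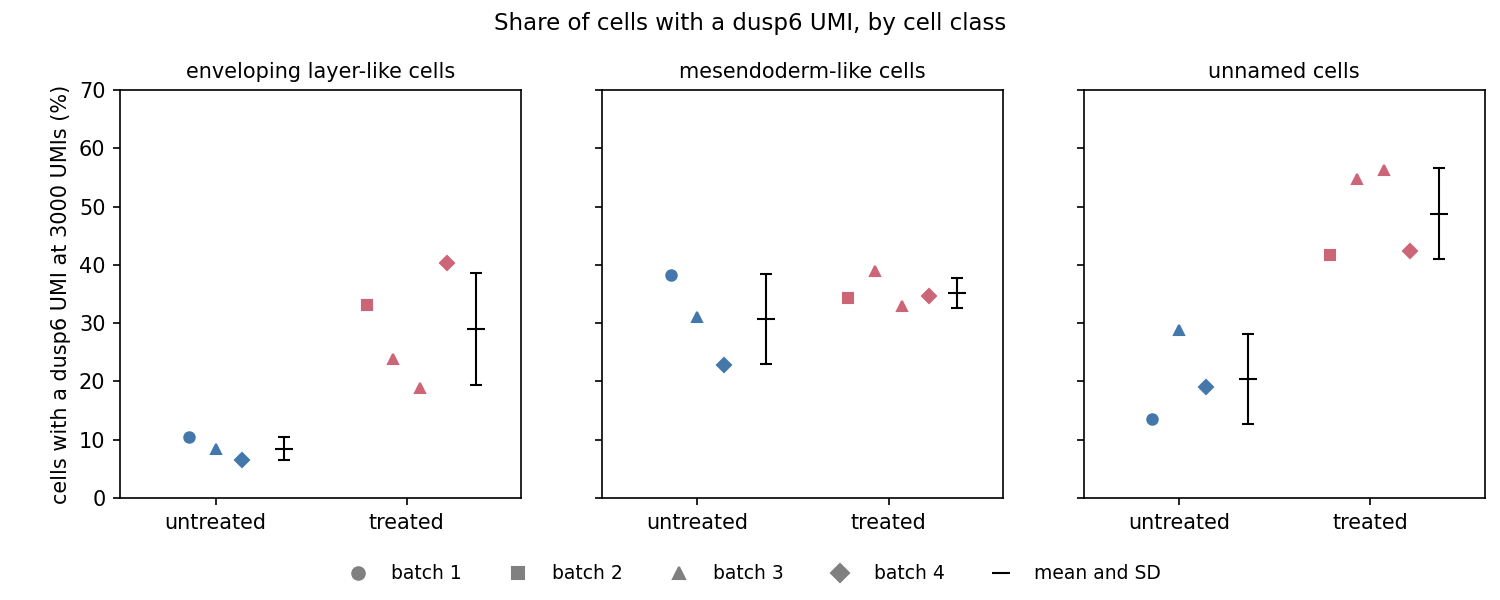
Percent of cells with at least 1 dusp6 UMI after thinning each cell to 3000 UMIs (vertical axis, from 0), for enveloping layer-like, mesendoderm-like and unnamed cells of untreated and treated libraries; each point is a library, its shape gives the batch, and the black bar is the mean with SD. Treated unnamed cells lie between 41.6% and 56.3%, and untreated ones between 13.5% and 28.8%.

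Enveloping layer-like cells made up 5.13% ± 1.30 (SD, n = 3) of untreated and 9.87% ± 2.74 (SD, n = 4) of treated cells, higher in every treated library (exact permutation p = 0.0571, adjusted over 6 classes p = 0.343). The difference was 5.39 percentage points within batch 3 and 2.63 within batch 4. The share rests on where the class ends, since library 7 had 7.40% at the main resolution, 40.0% at Leiden resolution 0.5 and 18.5% at 2.0. The class marker krt18a.1 was also higher outside the class, from 121 ± 15.7 to 422 ± 162 CPM. Mesendoderm-like cells were 15.8% ± 5.10 and 11.5% ± 4.64 (exact permutation p = 0.343). Their share was 20.2% in untreated against 16.4% and 12.6% in treated libraries of batch 3, and 16.9% against 5.21% in batch 4. Treated library 4 (11.7%) lay above untreated library 1 (10.2%). Germ cell-like clusters were found in libraries 1, 4 and 7 (21, 50 and 69 cells, 1.47% and 4.44% of the cells in the latter 2), stressed or dying cells-like clusters in libraries 1, 4, 5 and 6 (2.80%, 11.9%, 7.90% and 2.67%) and yolk syncytial layer-like clusters in libraries 2 and 5 (6.89% and 0.584%), with permutation p of 0.571, 0.400 and 0.857 by the exact test.

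Cells with a marginal gene (tbxta, tbx16 or mixl1) and an ectodermal gene (sox2, sox3 or zic2b) made up 79.5% ± 7.48 (SD, n = 3) of untreated and 68.7% ± 4.65 (SD, n = 4) of treated cells at 3000 UMIs (exact permutation p = 0.114). The share was 1.01 times the product of both single shares in untreated and 1.00 times in treated cells. A marginal gene was found in 54.9% ± 14.4 of untreated and 57.7% ± 17.1 of treated enveloping layer-like cells, which should lack such genes, and both kinds in 26.4% ± 11.9 and 40.2% ± 24.3, so a share with both is not read as expression of both in a cell. tbxta was found in 41.5% ± 5.06 and 58.9% ± 5.15 of cells and tbx16 in 88.9% ± 6.07 and 67.1% ± 8.76, with 15.7 and -10.2 percentage points within batch 3 and 16.0 and -26.8 within batch 4 (exact permutation p = 0.0571 each, adjusted over 10 measures p = 0.229). The tbx16 groups overlapped at 2000 UMIs (exact permutation p = 0.114) and without thinning, where the difference was -6.31 percentage points against -21.8 at 3000 UMIs (p = 0.171). The median distance to the nearest untreated cells was 8.93 ± 1.13 for untreated and 11.4 ± 0.588 for treated libraries, with a difference of 1.29 within batch 3 and 3.80 within batch 4 (exact permutation p = 0.0571). Without centring the distances were 13.0 ± 2.51 and 14.4 ± 1.29, and batch 3 differed by -0.503 (exact permutation p = 0.40).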

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

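The tests of the heat shock and p53 genes against library 4 and of all other splits of the libraries were chosen after the results were seen; the test without stressed or dying cells-like clusters was set out before its result, though as an added alternative. Of 86 sets of treated values examined for a library far from the others, 14 held one. Chance gives about 4.3 if the sets are independent and their values normal. In treated library 4 the summed cells stood apart for hsp70.3 (1850 CPM), hspa8b (198 CPM), hsp70.1 (69.2 CPM), hsp70l (53.5 CPM), tmem119b (59.5 CPM), bbc3 (19.6 CPM), btg2 (695 CPM) and fosl1a (28.5 CPM). Within classes, library 4 stood apart for hsp70.2 (137 CPM) and hspa8b (106 CPM) in enveloping layer-like cells and for hsp70l (63.7 CPM) and lmo2 (303 CPM) in unnamed cells. Library 4 is the only treated library of the larger feature table, and these values were not adjusted for an offset of that table. For btg2 the log2 difference of library 4 minus library 1 was 0.87, close to 0.88 within batch 3 and 0.70 within batch 4. For hsp70.3 it was larger, 6.46 against 4.08 and 3.41. Treated library 7 stood apart for foxd3 in enveloping layer-like cells (247 CPM), and treated library 5 was the 1 treated library with a yolk syncytial layer-like cluster (0.584% of cells).

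Several heat shock and p53 target genes stood apart in library 4, so that library alone could have made their rise. Batches 3 and 4 lack it, and there the median log2 difference of the 12 p53 targets was 0.73 within batch 3 and 1.23 within batch 4 with all 12 higher in each, which argues against library 4 as their only source, although none passed on those 5 libraries. For the 13 heat shock genes the medians were 0.67 and 0.16 with 12 and 8 members higher, so library 4 cannot be told apart as the source for that list as a whole, but hsp70.1, hspb1 and hsp70l passed with batch as replicate block in those batches (edgeR adjusted p = 0.030, 0.047 and 0.048), and the median of all 25 members was 0.79 there against 0.98 with all libraries. Without the cells of stressed or dying cells-like clusters the 5 called members still had a median of 3.12 and a lowest value of 1.1. This argues against those clusters as the only carriers for these 5 genes alone. They were picked for passing, and hsp70l and hsp70.1 were near 0 in untreated libraries (0.0987 and 0.392 CPM). For the other members no value without these cells is given, so the rise of the lists stays untested. Injection, handling of injected embryos, the construct and light differ together between the groups and stay open, as does an effect of MEK activity itself.

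gata2a was flagged because its change differed between enveloping layer-like and other cells by 2.56 on the log2 scale. In 4 of the 35 splits of the libraries as many genes were called, and the highest other split called 175 against 1 for the real one, so chance is not excluded, and the samples have a structure that the groups do not describe. The split with the highest count set libraries 1, 4 and 7 against the rest. It follows no single batch but holds together libraries 1 and 4, the libraries of the larger feature table. So does the split of libraries 1, 3 and 4, with 16 higher and 29 lower. The splits of libraries 1, 2 and 4, of 1, 4 and 5 and of 1, 4 and 6 do so too, with 0 higher and 0 lower each. Holding libraries 1 and 4 together therefore does not by itself give such calls. The fit has no term for a class difference that varies with the feature table, so these counts are not adjusted for one.

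Barcodes outside the cell filter, which entered only the alternative with all barcodes, had a higher treated than untreated mean for all 6 ERK feedback genes, and the groups were fully apart for 3. The lowest treated library had 139 CPM of dusp6, 108 CPM of spry4 and 54.8 CPM of spry2 there, above the highest untreated library at 103, 47.2 and 40.7 CPM. For etv4, etv5b and il17rd the groups overlapped across batches, with means of 229, 160 and 167 CPM in untreated and 529, 223 and 404 CPM in treated libraries. Within batches, etv4 stood at 348 CPM in untreated and at 745 and 830 CPM in treated libraries of batch 3 and at 254 and 386 CPM in batch 4, and il17rd at 337 against 535 and 756 CPM and at 144 against 276 CPM. etv5b stood at 219 against 281 and 280 CPM in batch 3 but at 133 against 124 CPM in batch 4.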

How the results depend on the processing

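The whole-embryo counts (95 genes higher, 34 lower) and the class counts depended on the settings. None of the 1191 alternative fold changes of the 71 tested pairs of a named gene and a cell set changed sign. Apart from the genes always named, these pairs were chosen for passing the threshold on these same libraries. A stable sign was therefore likely beforehand and does not measure how firm the changes are. Counts are given as higher and lower. Leaving out both batch 4 libraries, thinned sums, leaving out stressed or dying cells-like clusters, DESeq2 size factors in the class fits, doublets kept for ERK shares, most alternatives of single genes and lists and all settings of unnamed cells were chosen after seeing the data. The cause was not tested unless stated. Leaving out 1 library gave 1 to 164 and 0 to 118 genes for the whole embryo, 0 to 93 and 0 to 42 for enveloping layer-like, 0 to 88 and 0 to 85 for mesendoderm-like and 33 to 318 and 10 to 183 for unnamed cells, 0 to 3 gene lists and 0 to 1 genes for the class difference. Leaving out library 1 or 4 leaves 1 library on that feature table. In fits with the covariate that library adds nothing to the estimated effect, so they compare libraries of batches 3 and 4 alone. DESeq2 called 599 and 339 for the whole embryo, 139 and 50 for enveloping layer-like, 98 and 59 for mesendoderm-like and 651 and 359 for unnamed cells; on simulated counts it called 27 unchanged whole-embryo genes against 2 with edgeR. Its size factors in edgeR gave 5 lower genes in mesendoderm-like cells. No filter on low counts gave 148 higher genes for the whole embryo, 290 and 83 for enveloping layer-like and 146 and 102 for mesendoderm-like cells. No covariate gave 0 and 0 for the whole embryo and both classes and 2 and 2 for unnamed cells; in edgeR 517 and 257, 255 and 130, and 253 and 130 had an unadjusted p under 0.05. With batch as replicate block, on 5 libraries, the counts were 60 higher genes for the whole embryo, 196 and 111 for enveloping layer-like cells, 17 and 11 for mesendoderm-like cells and 2 lists. Of 70 pairs of a named gene and a cell set, 23 lost their call with the block. Without the covariate 65 of 71 lost it, and without both batch 4 libraries 45 of 71. Leaving out 1 library lost the call in 273 of 495 values. The block changed no call of the shares, which cannot pass 0.05. Libraries 5 and 6 summed gave 59 and 17, thinned sums 198 and 70, and leaving out stressed or dying cells-like clusters 19 lower genes. Without both batch 4 libraries there were 0 and 0 for the whole embryo, 146 and 18 for enveloping layer-like, 13 higher for mesendoderm-like and 75 and 32 for unnamed cells, 0 lists and 0 genes for the class difference. Leiden resolution 0.5 gave 10 and 3 for enveloping layer-like and 1 lower for mesendoderm-like cells, and 2.0 gave 22 higher for enveloping layer-like cells. Camera passed 9 lists with the preset and 0 with an estimated correlation. Differences of treated minus untreated in percentage points ran, leaving out 1 library, from 11.8 to 19.9 for any ERK feedback gene, 3.63 to 5.56 for the enveloping layer-like and -7.11 to -2.11 for the mesendoderm-like share, and -15.1 to -8.15 for co-detection, and from 2.14 to 3.14 for the distance. Not thinned, co-detection reversed to 0.797 and its ratio to the product to 0.00588, where depth differs between libraries; the yolk syncytial layer-like share differed by -3.30 to 0.146, reversed without untreated library 2. Cells in untreated libraries 2 and 3 were the shallowest, which limits what low genes can show there.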

Other observations

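The tests on cell classes, on both lists of ventral genes and of all other splits of the libraries were chosen after the results were seen; the tests between batches, of evenly spread RNA and of stressed cells for the first pattern were set out before.

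Some genes outside the fixed lists were low in untreated and higher in every treated library. The blood and vessel factor gene lmo2 stood at 0.714, 0.590 and 1.09 CPM in the untreated sums (without TMM adjustment) and at 212, 8.68, 11.5 and 48.6 CPM in treated libraries 4 to 7. The endothelial gene egfl7 (0.0376 to 0.174 against 1.24 to 11.2 CPM) lay the same way, as did the midbrain-hindbrain gene gbx2 (0.326 to 0.475 against 0.503 to 25.3 CPM) and the growth factor gene mdkb (0.564 to 5.55 against 10.3 to 30.5 CPM). These genes were picked after their values were seen, with no test of a shared function, and gbx2 was near the untreated range in library 5.

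In all, 30 genes had at least 10 CPM in library 4 and at most 1 CPM in library 1. A difference between batches 1 and 2 would place about 10% of them higher in all 3 treated than in both untreated libraries of batches 3 and 4, but 83.3% were (25 of 30, 95% interval 65.3% to 94.4%), against 12.3% of 7706 other genes, which argues against it. The interval takes the genes as independent, but they may vary together and include chaperone genes between which reads may have been split. Genes that moved as 1 block would all separate in about 10% of cases, so the evidence is weaker than the interval says. Cells with at least 3 of those 25 genes at 3000 UMIs were 0 of the untreated cells, which allows up to 0.0558%, 0.103% and 0.243% in libraries 1 to 3, and 29.8%, 2.46%, 5.68% and 14.9% of treated libraries 4 to 7; the 25 were chosen on these same libraries. The ratio to the share that independent draws give ran from 1.04 in library 4 to 3.16 in library 5. It reached neither bound set beforehand, so evenly spread free RNA cannot be told apart by it. The share was at least 3.12 times higher in unnamed than in mesendoderm-like cells in every treated library (Fisher's exact test on cells, which are not replicates, largest p = 0.00797). Free RNA would weigh more in shallow cells. Unnamed cells were shallower in libraries 5 and 7 (median 6871.5 and 7550 UMIs against 10483 and 36997), so the test cannot decide there. In libraries 4 and 6 the medians were close (29952.5 against 30383 and 7328 against 7650). There the difference in share argues against free RNA at a like share in every class. In libraries 4, 5 and 6, 14.4%, 18.7% and 3.41% of the cells with these genes lay in stressed or dying cells-like clusters (library 5 interval 11.3% to 28.2%). This argues against those clusters as the main carriers there. Library 7 had no such cluster and cannot decide. Stressed cells left unnamed were not tested. The share with these genes was higher in such clusters than in unnamed cells in library 5 (5.30% against 2.53%). It was also higher in library 6 (8.05% against 6.96%) and slightly lower in library 4. Injection, the construct, light and MEK activity differ together between the groups and stay open as the source.

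The fall of BMP and non-neural ectoderm genes could come from more enveloping layer cells diluting the rest. Among all cells outside that class, the median log2 fold change of the 7 called members was -2.01, against -2.02 in the sums of all cells. So the fall of these 7 was not confined to the class. It cannot decide on dilution, because the 7 were picked for falling in sums that cells outside the class dominate. The class held 4.06% of cells in library 2 and 13.2% in library 4, the lowest and highest shares. Its boundary also left enveloping layer-led clusters outside it. The 13 measured enveloping layer markers had a median of 0.93 in the summed cells, the direction that dilution needs, so a part of the fall may come from it. The median of all 24 members was at most -0.99 in each of the 3 differences between libraries of the same feature table, which argues against a difference between library batches. A response to MEK activity or to injection stays open, and the design does not part them.

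All 35 splits of the 7 libraries into 3 and 4 were run. For the whole embryo, 1 split, the real one, gave as many genes higher (95, highest other 4) and 1 as many lower (34, highest other 1), so chance is excluded as the source of these counts if every library can be exchanged for any other. The same held for the 5 gene lists that passed (1 split, highest other 1) and for unnamed cells, where 1 split gave as many higher (241, highest other 33) and 1 as many lower (83, highest other 1). Libraries of a batch resemble each other, and only 12 of the splits keep the number of untreated libraries in batch 3, in batch 4 and in batches 1 and 2 together. These are too few for a share under 0.05. Among them the highest other count was 0 higher and 0 lower for the whole embryo, for each class, for unnamed cells and for the lists. For enveloping layer-like cells, 2 splits gave as many higher (real 37, highest other 136) and 2 as many lower (real 6, highest other 17), the other one setting libraries 1, 3 and 7 apart. For mesendoderm-like cells, 3 splits gave as many higher (real 7, highest other 13) and 3 as many lower (real 3, highest other 15); 1 of them parts libraries 2, 5 and 6, all of batch 3, from the rest. Over all 35 splits chance is not excluded for either class, and a split with more calls than the real one points to a structure of the samples. Within batches 3 and 4, with batch as replicate block, the class counts were 196 and 111 for enveloping layer-like and 17 and 11 for mesendoderm-like cells.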
